A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

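Total RNA was isolated from subcutaneous tumours of H1975 cells, a human lung adenocarcinoma line, grown in male athymic nude mice. Per the labels, RNA of each group was hybridised as biotin-labelled cRNA to a human array (Illumina HumanWG-6 v3) and to a mouse array (Illumina MouseWG-6 v2). The human array is meant to read the tumour cells and the mouse array the stroma of the host. There were 11 arrays of each kind. Cediranib sensitive, cediranib resistant and vandetanib sensitive tumours had 3 arrays each, and vandetanib resistant tumours had 2. Neither a vehicle group nor untreated tumours are among the samples. The labels number replicates 1 to 3 and do not say that each is a separate animal, so p-values measure only the spread between samples.

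The deposited probe values are in intensity units on a linear scale and were not normalized between arrays. The authors also gave log2 values, which share a single distribution over all 11 arrays of a species. The ranks of these deposited log2 values within each array followed the intensities with a rank correlation of at least 0.999994 on the human arrays and 1 on the mouse arrays. The scanner software and the steps from scan to table are not given in the sources used here. Intensities carried neither detection p-values nor control probes.

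Intensities were background corrected by normexp with an offset of 50 and quantile normalized over the 11 arrays of the species with limma 3.58.1 in R 4.3.3. Detection was estimated: the mode and the left side of each array's log2 intensities gave a background distribution, and a probe counted as detected when its p under that distribution was under 0.05. This stands in for the detection p-values that the plan called for. A probe was kept when detected on at least 2 of 11 arrays and when it named 1 gene. Of 48803 human probes 27578 named 1 symbol, and of 45281 mouse probes 34885 did. Mouse symbols were updated by gene identifier from a RefSeq gene table on GRCm38.p6, which also gave positions. Human symbols stayed as the array annotation gives them. The probe with the highest mean stood for each gene, which left 13601 human and 13180 mouse genes. A gene is called "not above background" in a group when no array of that group detected the probe that stands for it. A fold change against such a group is given as a lower bound on the normalized scale.

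Arrays that match within noise were averaged and counted as 1 sample. The measure was the spread of the log2 difference between 2 arrays over probes brighter than 500 on both, set against the spread of dim probes. On the human arrays cediranib sensitive 1 and 2 differed by 0.106 (noise 0.177). On the mouse arrays cediranib sensitive 1 and 2 differed by 0.131 (noise 0.217) and vandetanib sensitive 1 and 2 by 0.0787 (noise 0.227). The other within-group pairs with signal differed by 0.209 to 0.806. The model therefore held 10 human and 9 mouse samples. This averaging was decided after the arrays had been compared and after the counts with all arrays separate had been seen. The comparisons had been planned with separate arrays, and both sets of counts are given. Vandetanib sensitive 2 and 3 on the mouse arrays also lay under the noise (0.209 against 0.220) while 1 and 3 lay just above it (0.229 against 0.224), so an added alternative averaged all 3.

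Groups were compared with limma's moderated test (two-sided) in a means model of the 4 groups per species. The comparisons were resistant against sensitive under cediranib and under vandetanib, the mean of these, their difference (vandetanib minus cediranib), and vandetanib sensitive against cediranib sensitive. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 18 human and 23 mouse, were fixed before the data were examined. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. On the mouse arrays the mean residual correlation of members within groups lay above this preset in most lists. It was 0.396 for interferon, 0.285 for macrophage and 0.197 for cell cycle genes. The p-values with the preset are too small for such lists, and "rose" or "fell" of a list is to be read with both p-values. Named genes followed a rule also fixed before the data were examined. It takes up to 8 called genes in each direction with groups that do not overlap, or the 10 smallest p where fewer than 10 were called. To these it adds HGF, MET, EGFR, VEGFA and KDR and up to 4 members of each list. For the mean, the difference and the drug comparison it takes 4 in each direction, or the 4 smallest p.

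The alternatives tried were the log2 values the authors gave, no background correction, median scaling, no filter or a strict filter, the mean of a gene's probes, only the compared groups in the fit, a trended robust variance, array weights, the replicate number as a block, and leaving out each sample in turn. Alternatives added after seeing the data kept all arrays separate, averaged vandetanib sensitive 1 to 3, used only the human arrays with signal, or took the means of the skin and skeletal muscle lists as covariates. On data simulated from the residual spread of the mouse arrays, 20.7% of 92 genes shifted by 1 log2 unit and 86.1% of 108 genes shifted by 2 were called, with 5 false calls. On the 5 human arrays with signal, none of the 94 and 106 shifted genes was called. For arrays, their number limits the precision.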

Results

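H1975 is a human lung adenocarcinoma line. Its subcutaneous xenografts in male athymic nude mice were treated by mouth each day with cediranib at 6 mg/kg or vandetanib at 50 mg/kg. Both are quinazoline kinase inhibitors. Cediranib acts on the vascular endothelial growth factor (VEGF) receptors and vandetanib on these and on the epidermal growth factor (EGF) receptor. Tumours called sensitive were treated for 14 days from a volume of about 350 mm3, and tumours called resistant were treated from about 270 mm3 until their volume had tripled. Each group was read on a human array, for the tumour cells, and on a mouse array, for the host stroma, with 3 arrays per group except 2 for vandetanib resistant tumours. The title of the series names hepatocyte growth factor (HGF) and its receptor c-MET in resistance to VEGF receptor inhibitors, and the design calls for both species in sensitive and resistant tumours.

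Signal differed between groups on both arrays. On the mouse arrays the mean intensity above background per probe was 291 ± 103 units (SD, 3 arrays) in cediranib sensitive tumours and 40.1 ± 12.3 (3 arrays) in cediranib resistant ones, a ratio of 7.27. It was 228 ± 25.5 (3 arrays) in vandetanib sensitive and 108 ± 35.1 (2 arrays) in vandetanib resistant tumours, a ratio of 2.12. On the human arrays 5 of 11 carried probe-specific signal: cediranib sensitive 1 to 3 and cediranib resistant 1 and 2, with brightest probes between 4055 and 21950. Cediranib resistant 1 was the weakest of these, with 99% of probes at or under an intensity of 194. The other 6, which are cediranib resistant 3 and all 5 vandetanib arrays, had brightest probes between 101 and 1025, and their ranks correlated with those of any array by at most 0.00998 in size. Cediranib sensitive 1 and 2 matched within noise on both arrays, as did vandetanib sensitive 1 and 2 on the mouse array. Each such pair was averaged and counts as 1 sample in every n of a log2 level, a choice made after the counts with all arrays separate had been seen.

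**Figure D1:**
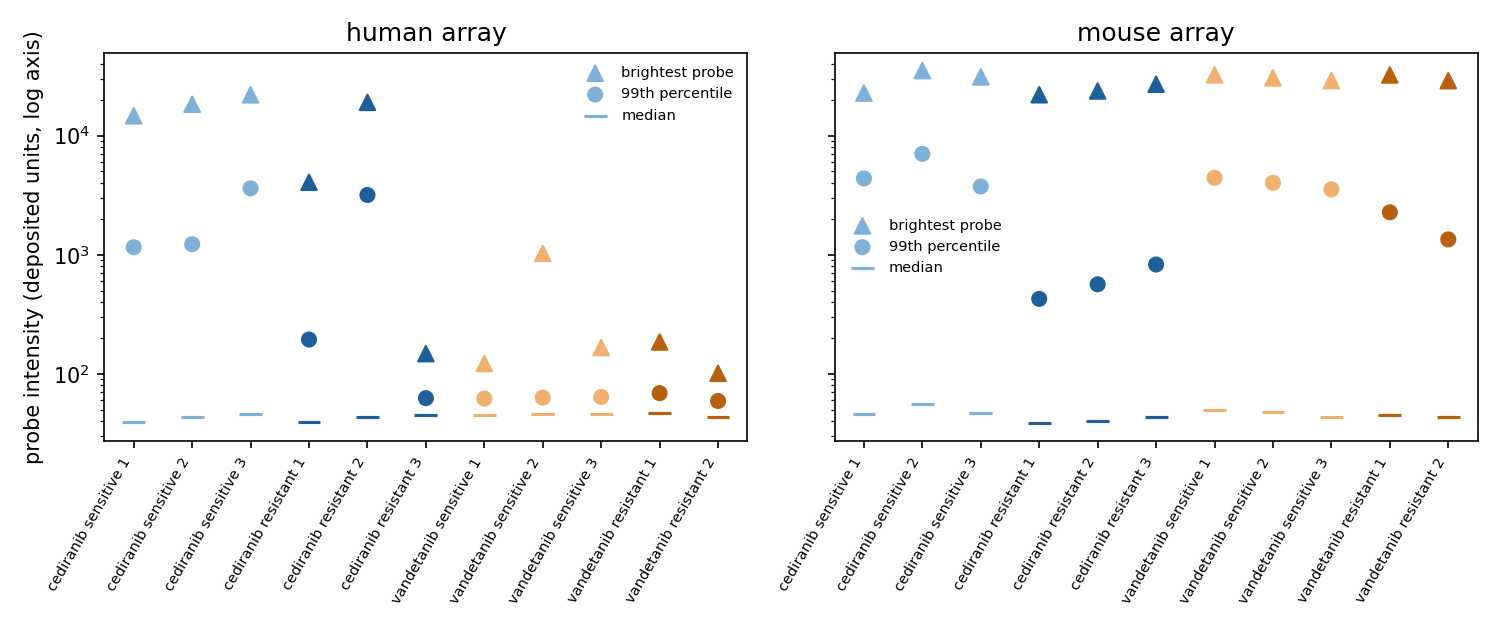
Median, 99th percentile and brightest probe of each array in deposited intensity units (log axis), for the human and the mouse arrays, colored by group. On the human side cediranib resistant 3 and the 5 vandetanib arrays lie far below the others, and on the mouse side the 99th percentile is lowest in cediranib resistant tumours.

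The first question is whether the tumour cells differed between cediranib resistant and sensitive tumours. MMP1, a collagenase, fell by 3.37 log2 units (SE 0.27), LAD1, a basement membrane anchoring protein, fell by 3.08 (SE 0.29), and S100A8, a calcium-binding protein of squamous and myeloid cells, fell by 4.97 (SE 0.50). S100A7, a keratinocyte protein, was at least 15.4-fold lower and not above background in the resistant group. ADIRF fell by 3.01 (SE 0.32) and the lipase CEL fell by 2.38 (SE 0.27). These 6 genes, all lower, were the calls by limma among 13601 genes (adjusted p 0.0215 to 0.0467), and 450 genes had an unadjusted p under 0.05. The groups counted 2 samples, of which 1 is the averaged pair, and 3 arrays, of which 1 had no probe-specific signal. The spread behind each SE was pooled with the vandetanib arrays, which had no such signal either. With only the compared groups in the fit 0 genes were called. Whether mouse RNA on human probes added to these values was not tested. MYL1, a gene of skeletal muscle, was at an intensity of 1233 on human array cediranib resistant 1 and 46.0 on cediranib resistant 2. On the mouse arrays of the same names the skeletal muscle list was at 1.54 and −4.92 relative to each gene's mean. Mouse RNA on human probes is therefore not excluded for the 6 called genes. The count was 10 without cediranib resistant 1, 0 to 2 on leaving out any other sample, 0 with the log2 values the authors gave and 13 with all arrays separate.

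The HGF probe used in the fit, ILMN_1801586, was not above background in either cediranib group on the human array. Another, ILMN_1790149, was detected in cediranib resistant 2 at an intensity of 48.0 against a background of 40.4. It also counted as detected on vandetanib resistant 1, an array without probe-specific signal, at 56.8. On the human arrays without such signal 10.8% to 13.5% of probes counted as detected, so this is not read as HGF expression. MET, the receptor of HGF, gave −0.63 (SE 0.47), EGFR −0.94 (SE 0.51) and VEGFA 0.09 (SE 0.27), and none was called. KDR, a VEGF receptor, was not above background in either group. Lists were tested for shifts as groups. Squamous and keratinization genes were called lower as a list, at a median of −0.14 where that of all genes was −0.078. Of 13 measured members 2 were called and 3 "adjusted over the list alone" (camera adjusted p = 0.00276, and 0.127 with an estimated correlation). Epithelial markers (median −0.64), cell cycle genes (−0.44), interferon response genes (−0.62), glycolysis enzymes (−1.13) and p53 targets (−0.64) were the other lists called lower, with adjusted p from 0.00765 to 0.0429. With an estimated correlation their adjusted p lay between 0.495 and 0.723. With only the 5 arrays that carried signal none of these 5 lists was called (adjusted p 0.0534 to 0.795). With samples left out, glycolysis (0.05), p53 (−0.08) and cell cycle genes (−0.20) were not called without cediranib resistant 3, cell cycle and interferon genes (−0.61 and −0.64) without cediranib resistant 2, p53 targets (−0.63) and squamous genes (−0.06 against −0.14) without cediranib resistant 1, cell cycle (−0.49), glycolysis (−0.81) and interferon genes (−0.42) without cediranib sensitive 3, and p53 targets without cediranib sensitive 1-2 (−0.48) or 4 of the 5 vandetanib arrays. Epithelial markers stayed called without each sample, with −1.22 without cediranib resistant 2. Interferon genes gave −0.33 without cediranib resistant 3, cell cycle genes −0.67 without cediranib resistant 1, and squamous genes −0.25, −0.21 and −0.30 without cediranib sensitive 1-2, cediranib sensitive 3 and cediranib resistant 2.

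With only the 5 human arrays that carried signal, a fit chosen after seeing the data, no gene of 11399 was called by limma, while 625 had an unadjusted p under 0.05. The smallest p belonged to CLCA2, a chloride channel regulator of squamous epithelia, which was at least 23.7-fold lower. MMP1 gave −4.29 (SE 0.37), LAD1 −3.65 (SE 0.40), CEL −3.24 (SE 0.29), and S100A7 was at least 32.3-fold lower. DST, a cytoskeletal linker, gave −2.80 (SE 0.27), and the chemokine CX3CL1 was at least 5.30-fold lower. Hypoxia response genes rose as a list (27 members, median 0.35, adjusted p = 1.06e-06; adjusted p = 0.467 with an estimated correlation). Among its members ANGPTL4 gave 1.78 (SE 0.35), ADM, the vasodilator adrenomedullin, 1.39 (SE 0.47), SLC2A3, a glucose transporter, 1.03 (SE 0.28) and NDRG1 0.94 (SE 0.28). Squamous genes fell as a list (median −0.54, adjusted p = 0.0012; adjusted p = 0.513 with an estimated correlation), with KRT5 at least 4.89-fold lower. Cholesterol synthesis genes rose (median 0.22, adjusted p = 0.00729; adjusted p = 0.749 with an estimated correlation), with DHCR7 at 1.35 (SE 0.27). The squamous list was not called without cediranib resistant 1 (−0.30) and gave −2.36 without cediranib resistant 2, −0.83 without cediranib sensitive 3 and −0.31 without cediranib sensitive 1-2. The cholesterol list was not called without cediranib sensitive 1-2 (0.22) or cediranib resistant 2 (−0.09) and gave 0.60 without cediranib resistant 1, and hypoxia genes gave 0.58 without cediranib sensitive 3. Hypoxia genes had a median of −0.06 and cholesterol genes of 0.01 with all arrays, where neither list was called. MET gave −0.18 (SE 0.38) and EGFR −0.66 (SE 0.51).

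For vandetanib, the human arrays of both groups lacked probe-specific signal. The fit called 19 genes higher and 0 lower, with 605 at an unadjusted p under 0.05, and gave HGF −2.08 (SE 0.57, adjusted p = 0.440) and MET 0.00 (SE 0.47). These values describe arrays without signal and are not read here as tumour cell expression. The same holds for the mean over both drugs (0 called by limma, 453 at unadjusted p under 0.05), for the difference between drugs (0 called, 506) and for vandetanib sensitive against cediranib sensitive tumours (1 higher and 68 lower, 3080), where the lower group is made of arrays without signal.

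In the stroma of cediranib resistant against sensitive tumours, keratins and other hair and skin genes were much lower. Krt34, a hair keratin (chromosome 11, 100037347 to 100041554), fell from a log2 level of 10.42 ± 0.44 (SD, n = 2) to 6.21 ± 0.13 (n = 3; SE of the change 0.24, adjusted p = 0.00131). Krt71, Krt27 and Krt28, keratins of the inner root sheath of the hair, had changes of −4.99, −4.95 and −4.58, and Lor, Rptn and Lce1f, of the cornified envelope and upper epidermis, of −3.19, −3.93 and −4.18, all called. Among members of the cell cycle list that were called, the changes were −1.76 (SE 0.25) for Top2a, −1.62 (SE 0.28) for Mcm7 and −1.21 for both Pcna and Mcm4. Interferon-induced Zbp1 was higher by 1.52 (SE 0.15), and Flt1, the VEGF receptor 1 (chromosome 5, 147561604 to 147726438), by 2.02 (SE 0.44).

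limma called 777 of 13180 mouse genes, 199 higher and 578 lower, of which 485 changed by over 1 log2 unit, and 3357 had an unadjusted p under 0.05. The highest changes were Ccdc144b (3.90, SE 0.62), Gm10125 (3.56, SE 0.72), the steroid dehydrogenase Hsd3b2 (3.50, SE 0.62) and the antiviral protein Zc3hav1 (2.71, SE 0.54). Nnt, a mitochondrial transhydrogenase, was at least 6.60-fold higher. Ctcfl (2.49), the potassium channel Kcnc4 (2.40) and the tendon transcription factor Scx (2.39) followed. S100a3 (−4.78) and Lce1c (−3.98) were among the lowest.

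By list, skin and hair genes (18 measured, 7 called lower, 15 "adjusted over the list alone", median −2.31) and cell cycle genes (26 measured, 8 called lower, 14 "adjusted over the list alone", median −0.85) fell, each with a camera adjusted p of 4.7e-07 (adjusted p = 0.639 with an estimated correlation). Mouse orthologs of tumour cell epithelial genes, a list meant to track human RNA on mouse probes, had a median of −0.58 and were not called (14 measured, adjusted p = 0.375). Relative to each gene's mean over arrays, this list was at 0.48, 0.47 and 0.20 in cediranib sensitive 1 to 3, and cell cycle genes at 0.73, 0.75 and 0.31. In cediranib resistant 1 to 3 it was at 0.18, −0.20 and −0.46, and cell cycle genes at −0.16, −0.37 and −0.11. Whether human RNA added to the cell cycle values was not tested. Interferon response genes (23 measured, 2 higher, 3 "adjusted over the list alone", median 0.79) and endothelial markers (22 measured, 1 higher, 0 "adjusted over the list alone", median 0.96) rose, each with adjusted p = 7.43e-05 (adjusted p = 0.689 with an estimated correlation). Xaf1, of the interferon list, was at least 2.31-fold higher. Tip cell and sprouting genes (15 measured, 0 called, median 0.83) rose with adjusted p = 0.0021 (adjusted p = 0.689 with an estimated correlation). Cediranib resistant 1 did not share the rise of these 2 vascular lists: relative to each gene's mean over arrays, the mean of the endothelial list was −0.73 in it, 0.74 and 0.82 in cediranib resistant 2 and 3, and −0.80 to −0.34 in the sensitive arrays, and that of the tip cell list was −0.74, 1.08 and 0.56, against −0.53 to −0.44. Without cediranib resistant 2 the tip cell median was 0.37 and not called, and without cediranib resistant 1 it was 1.38. The endothelial median was 0.61 without cediranib resistant 3 and 0.56 without cediranib sensitive 1-2. The interferon median fell to 0.30 without cediranib resistant 3, still called. Hypoxia genes rose as a list (26 measured, median 0.39, adjusted p = 0.0239; adjusted p = 0.639 with an estimated correlation), although the single member called, the mitophagy receptor Bnip3l, fell by 0.80. This list was not called without cediranib resistant 2 (0.32) and gave 0.25 without cediranib sensitive 3. Under median scaling, where the median of all genes was −1.22 rather than −0.06, the medians of interferon (−0.40), endothelial (−0.90) and tip cell genes (−1.10) turned negative but lay above that of all genes. Skin (−4.52), cell cycle (−2.03) and hypoxia genes (−1.74) lay below it, so that hypoxia turned from up to down.

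Single genes of lists that were not called also passed the test. Plin4 (1.15, SE 0.23) and Lep (1.13, SE 0.24), both of adipocytes, the NF-kB target Tnfaip2 (1.74, SE 0.29), Timp1, an inhibitor of matrix proteases (1.27, SE 0.25), and Elf3 (0.76, SE 0.17) were higher. H2-Ab1, an antigen presentation gene, was lower (−1.07, SE 0.23), as were Ccl2 (at least 1.59-fold), Mpo (at least 1.29-fold) and Epcam (at least 1.09-fold). Ccl2, Mpo and Epcam were not above background in the resistant group. The mouse arrays of that group detected a mean of 33.2% of probes, against 46.2% in cediranib sensitive tumours. A weak probe can thus drop under background there through the lower signal of the arrays, and these bounds hold for normalized levels only. The count rested on the pooled spread and on the averaging. It was 0 with only the compared groups in the fit, 0 with the skin and muscle list means as covariates, 14 without vandetanib sensitive 1-2 or 3 or with these averaged, 40 without cediranib sensitive 3, 178 without cediranib resistant 3, 252 without cediranib sensitive 1-2, 274 without either vandetanib resistant array, 2246 without cediranib resistant 1, and 3094 (955 higher, 2139 lower) with all arrays separate. Under median scaling 38 genes were higher and 8663 lower, and Flt1, Zbp1, Kcnc4, Plin4, Lep, Tnfaip2, Timp1 and Elf3 had negative changes, from −0.16 to −1.50.

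**Figure D2:**
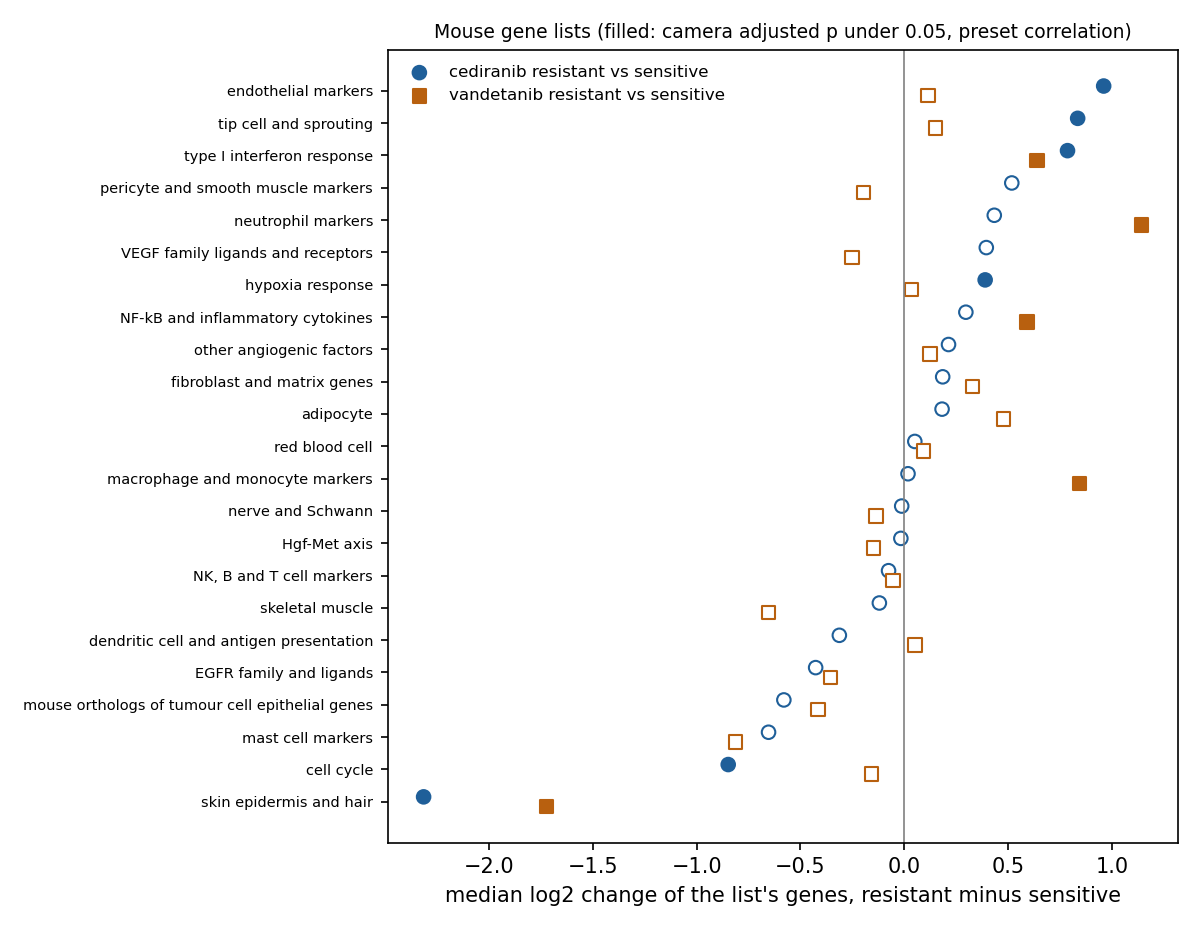
Median log2 change, resistant minus sensitive, of the genes of each mouse list under cediranib and under vandetanib, with filled symbols where camera's adjusted p with the preset correlation is under 0.05. Skin and hair genes lie lowest under both drugs, at −2.31 and −1.72, and interferon genes lie at 0.79 and 0.64, where median scaling gives −0.40 and 0.01.

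In the stroma of vandetanib resistant against sensitive tumours, Tchhl1, a trichohyalin-like gene of hair and skin (chromosome 3, 93468754 to 93471980), was the single call: it was at least 7.72-fold lower (log2 change −3.00, SE 0.24, adjusted p = 0.0443) and not above background in the resistant group. Interferon response, macrophage, NF-kB and neutrophil genes rose as lists, and skin and hair genes fell. With an estimated correlation each of the 5 lists had adjusted p = 0.588. Interferon genes had a median of 0.64 over 23 genes (adjusted p = 9.15e-09), with Rsad2, an antiviral enzyme, at 2.37 (SE 0.88) and Zbp1 at 0.90 (SE 0.17). Macrophage and monocyte markers had a median of 0.84 over 20 genes (adjusted p = 3.56e-07), with the complement gene C1qa at 2.21 (SE 0.57), Arg1 at 2.40 (SE 0.96) and Cd14 at 1.79 (SE 0.57), and the median was 0.55 without vandetanib resistant 1. NF-kB and inflammatory cytokine genes had a median of 0.59 over 25 genes (adjusted p = 9.85e-06), with the chemokines Ccl4 at 2.63 (SE 0.85) and Ccl3 at 2.41 (SE 0.89). The mean of this list relative to each gene's mean over arrays was 0.18 in vandetanib resistant 1 and 0.76 in vandetanib resistant 2, and its median was 0.46 without the latter.

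Neutrophil markers had a median of 1.14 over 11 genes (adjusted p = 0.000799), with Retnlg at 1.42 (SE 0.35) and Lcn2 at 1.02 (SE 0.39), and the median was 0.71 without vandetanib resistant 2. Skin and hair genes had a median of −1.72 over 18 genes (adjusted p = 1.07e-05), and 8 of them were lower "adjusted over the list alone". That median was −0.79 without vandetanib resistant 1 and −2.62 without vandetanib resistant 2. limma called 0 genes higher and 1 lower of 13180, and 1501 had an unadjusted p under 0.05. The smallest p after Tchhl1 belonged to Atp1b4 (−1.59, SE 0.18), Krtap6-5 (at least 2.22-fold lower), the Fc receptor gene Fcgr4 (1.90, SE 0.23), the interferon-induced GTPase Igtp (1.83, SE 0.22), Tubb2b (−1.24, SE 0.15), Atp6v1a (2.03, SE 0.25) and Smarca5-ps (1.51, SE 0.20), and none was called. Plau, the urokinase that can activate HGF, gave 2.09 (SE 0.48) and was not called. The mean of the Hgf-Met axis list, relative to each gene's mean over arrays, was −0.27 and 0.10 in vandetanib resistant 1 and 2. In vandetanib sensitive arrays it was −0.13 to 0.01.

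Tchhl1 was not called without cediranib sensitive 1-2 or 3, cediranib resistant 1 or 3, or any vandetanib sample, nor with the log2 values the authors gave, with adjusted p from 0.0578 to 0.615 and log2 changes from −2.79 to −3.21. With all arrays separate 52 genes were higher and 154 lower, and under median scaling, where the median of all genes was −0.63, 22 were higher and 4706 lower and the medians of interferon, macrophage, neutrophil and NF-kB genes were 0.01, 0.06, 0.32 and −0.01.

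Over both drugs, the normalized level of Hgf, the ligand of c-MET, was higher in the stroma of resistant tumours. Its deposited intensity was lower in resistant tumours under cediranib, as given below. The mouse gene lies on chromosome 5 from 16553495 to 16619439, and the probe ILMN_1237666 detected it on all 11 arrays. Normalized log2 levels were 6.54 ± 0.05 (SD, n = 2) in cediranib sensitive, 7.25 ± 0.06 (n = 3) in cediranib resistant, 6.70 ± 0.46 (n = 2) in vandetanib sensitive and 7.86 ± 0.09 (n = 2) in vandetanib resistant tumours. The mean change over both drugs was 0.93 (SE 0.15, adjusted p = 0.0293), and it was called. The change was 0.71 under cediranib (SE 0.20, 95% interval 0.24 to 1.18, adjusted p = 0.0823) and 1.16 under vandetanib (SE 0.22, 95% interval 0.64 to 1.68, adjusted p = 0.220), and neither was called on its own. The deposited intensity of the probe was 107 ± 33.5 (3 arrays) in cediranib sensitive, 53.8 ± 6.80 (3) in cediranib resistant, 113 ± 41.3 (3) in vandetanib sensitive and 125 ± 20.4 (2) in vandetanib resistant tumours. As a share of the array's signal above background it was 4.699 ± 0.676, 8.52 ± 0.306, 6.70 ± 3.20 and 17.7 ± 1.70 ppm, and vandetanib sensitive 1 and 2, at 8.56 and 8.53, lay apart from 3, at 3.01.

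Median scaling gave Hgf a mean change of −0.08 and −0.51 under cediranib, where the medians of all genes were −0.95 and −1.22, so it lay above these medians, on a probe near background in cediranib resistant tumours (intensity 48.1 to 61.3 against a background of 36.7 to 40.02). The call was lost without cediranib sensitive 1-2 or 3, cediranib resistant 3, or any vandetanib sample (adjusted p 0.0579 to 0.120), and with vandetanib sensitive 1 to 3 averaged (adjusted p = 0.109) or with the skin and muscle covariates (adjusted p = 0.864, at a mean change of 0.91). Another Hgf probe, ILMN_2729117, detected on 7 arrays, gave 0.04 under cediranib and 0.16 under vandetanib, and ILMN_2580097 was detected on 0 arrays. The Hgf-Met axis list did not rise with Hgf. Relative to each gene's mean over arrays, its mean was −0.09 to 0.07 in cediranib resistant and 0.04 to 0.16 in cediranib sensitive arrays. Under vandetanib, as given above, the resistant arrays lay on both sides of the sensitive ones. Met was detected on 1 mouse array and gave 0.21 (SE 0.15) under cediranib and 0.11 (SE 0.16) under vandetanib without the detection filter. Kdr, detected on 1 array, gave 0.16 (SE 0.10) and 0.08 (SE 0.11). Egfr gave −0.45 (SE 0.24) and −0.42 (SE 0.26), while its other probes detected on 11 arrays differed in sign: ILMN_3052260 gave 0.68 and 0.02, ILMN_3128725 0.11 and 0.14, and ILMN_2693922 −0.93 and −0.50.

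**Figure D3:**
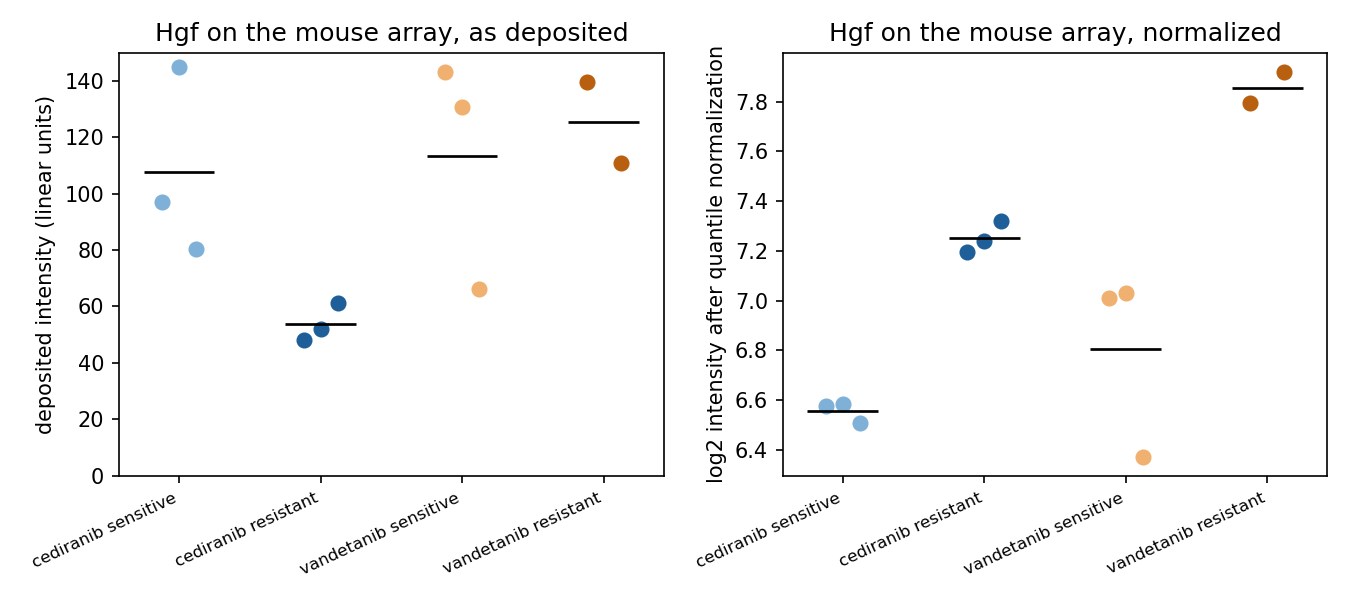
Hgf on each mouse array by group, as deposited intensity and as normalized log2 level, with a line at the mean over the arrays of each group. The log2 levels given here count each averaged pair as 1 sample, so a line can differ from them. The normalized level is higher in both resistant groups (7.25 and 7.86) than in the sensitive groups (6.54 and 6.70), while the deposited intensity is lowest in cediranib resistant tumours at 53.8 and median scaling gives a mean change of −0.08, where the median of all genes is −0.95.

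The mean over both drugs called 575 mouse genes, 109 higher and 466 lower, of which 235 changed by over 1 log2 unit, and 3371 had an unadjusted p under 0.05. Krt27 (−4.56, SE 0.63), Krt71 (−4.32, SE 0.77), Prr9 (−4.31, SE 0.76) and Krt28 (−3.74, SE 0.58) were lowest, and Gm7609 (3.47, SE 0.62), Hsd3b2 (3.37, SE 0.46), Ccdc144b (3.33, SE 0.46) and Pisd-ps2 (3.29, SE 0.67) were highest. Across genes the changes under the 2 drugs, which share no arrays, had a correlation of 0.417, and genes are not independent replicates. All arrays were quantile normalized together and resistant arrays were dimmer under both drugs. What this adds to the correlation was not tested. Interferon genes (median 0.78, adjusted p = 2.13e-08, 3 of 23 called and 8 "adjusted over the list alone"), NF-kB genes (0.43, adjusted p = 0.000369), macrophage (0.41, 0.00134) and neutrophil markers (0.73, 0.00278) rose as lists. Endothelial (0.55, 0.000217), tip cell (0.49, 0.00271), hypoxia (0.14, 0.0105) and adipocyte genes (0.45, 0.0105) rose as well, while skin (−2.11, 9.28e-08) and cell cycle genes (−0.49, 0.000162) fell. With an estimated correlation the adjusted p of these 10 lists lay between 0.528 and 0.597. The rise of endothelial and tip cell genes was absent in cediranib resistant 1, as given above, and their medians were 0.86 and 0.77 without it, with tip cell genes at 0.27 without cediranib resistant 2. Adipocyte genes were not called without vandetanib resistant 1 (0.13) or cediranib resistant 1 (0.27), macrophage markers not without cediranib sensitive 1-2 (0.06; 0.80 without cediranib sensitive 3) and hypoxia genes not without vandetanib resistant 2 (0.13), while these gave 0.21, 0.25 and 0.24 without cediranib sensitive 1-2, cediranib resistant 1 and vandetanib resistant 1. NF-kB genes gave 0.20 without cediranib resistant 3 and cell cycle genes −0.32 without cediranib sensitive 1-2.

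The count of the mean was 253 without cediranib sensitive 1-2, 294 without cediranib sensitive 3, 182 without cediranib resistant 3, 2256 without cediranib resistant 1, 4 without vandetanib sensitive 1-2 or 3, 3 without vandetanib resistant 1 and 116 without vandetanib resistant 2. It was 3204 (857 higher, 2347 lower) with all arrays separate, 0 with the skin and muscle covariates, and 60 higher and 8992 lower under median scaling. There the median of all genes was −0.95, those of interferon (−0.28), NF-kB (−0.27), neutrophil (−0.18), tip cell (−0.70), macrophage (−0.88) and endothelial genes (−0.91) lay above it, and hypoxia (−1.19) and adipocyte genes (−1.16) lay below it.

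Whether the stroma changed differently under the 2 drugs was tested as the difference, vandetanib minus cediranib. limma called 0 of 13180 mouse genes, with 1411 at an unadjusted p under 0.05. The smallest p belonged to the lens crystallin gene Cryba4 (2.26, SE 0.24), the phosphatase Dusp3 (−1.99, SE 0.23), Lynx1 (−2.20, SE 0.27) and Flot1 (−1.93, SE 0.24), each with adjusted p = 0.251. Hgf differed by 0.45 (SE 0.30, 95% interval −0.25 to 1.15, adjusted p = 0.619), so that a difference of up to 1.15 was not excluded. Vegfa gave 1.05 under cediranib (SE 0.28, adjusted p = 0.0685) and −0.13 under vandetanib (SE 0.30), a difference of −1.18 (SE 0.41, adjusted p = 0.404). Another probe detected on 11 arrays, ILMN_3121255, gave 0.75 and −0.29. The deposited intensity of the probe in the fit was 849, 1720 and 412 in cediranib sensitive 1 to 3. In cediranib resistant 1 to 3 it was lower, at 179, 145 and 248, so the 1.05 is a change of the normalized level alone.

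By list, cell cycle genes moved up in vandetanib relative to cediranib (median 0.63, adjusted p = 1.25e-06; adjusted p = 0.779 with an estimated correlation). Macrophage markers did too (median 0.94, adjusted p = 0.00802; adjusted p = 0.977 with an estimated correlation), and endothelial markers moved down (median −0.73, adjusted p = 0.0432; adjusted p = 0.977 with an estimated correlation). Macrophage markers were not called without cediranib sensitive 3 (0.32) and gave 1.64 without cediranib sensitive 1-2 and 0.62 without vandetanib resistant 1, and cell cycle genes gave 0.36 without cediranib sensitive 1-2. Endothelial markers were not called without cediranib sensitive 1-2 (−0.52), cediranib resistant 2 (−0.48) or 3 (−0.39) or vandetanib sensitive 3 (−0.85), and gave −1.29 without cediranib resistant 1. Under median scaling the median of all genes was 0.50 and these medians were 1.28, 1.82 and −0.02. With all arrays separate 72 genes were higher and 97 lower, and under median scaling 758 were higher and 31 lower.

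Vandetanib sensitive and cediranib sensitive tumours were compared after 14 days of each drug, at doses of 50 and 6 mg/kg that differ. In vandetanib sensitive stroma Lynx1, a modulator of nicotinic receptors, was higher by 2.31 (SE 0.20), Adamtsl4 by 2.06 (SE 0.21), Atp1b4, a muscle protein, by 1.71 (SE 0.18) and Drp2, a dystrophin-related protein, by 1.68 (SE 0.16), and Cryba4 was lower (−1.77, SE 0.18), each with adjusted p = 0.0478. These are 5 of the 6 genes called by limma, of which 5 were higher and 1 lower, and 1573 had an unadjusted p under 0.05. Hgf gave 0.15 (SE 0.22, 95% interval −0.36 to 0.67) and Vegfa 1.303 (SE 0.30, adjusted p = 0.197).

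Cell cycle genes were lower as a list in vandetanib sensitive tumours (median −0.77, adjusted p = 7.68e-13, 11 of 26 lower "adjusted over the list alone"; adjusted p = 0.234 with an estimated correlation), as were skin and hair genes (median −1.52, adjusted p = 7.12e-06; adjusted p = 0.791 with an estimated correlation). Endothelial markers (median 0.76, adjusted p = 0.00066), skeletal muscle genes (2.20, 0.00372) and pericyte markers (0.40, 0.0345) were higher (adjusted p = 0.791 with an estimated correlation), as were VEGF family genes (0.64, 0.00372; adjusted p = 0.234 with an estimated correlation). The directions of these 6 lists were the same under median scaling. Without cediranib sensitive 1-2 endothelial (0.52), skeletal muscle (2.09) and pericyte genes (0.40) were not called and cell cycle genes gave −0.51, and pericyte genes were not called without cediranib resistant 3 (0.40) or vandetanib sensitive 3 (0.43) either. The gene count was 68 without cediranib sensitive 1-2, 3 without cediranib sensitive 3, 35 and 86 without cediranib resistant 1 and 2, and 0 without cediranib resistant 3 or any vandetanib sample. It was 0 with the log2 values the authors gave and 966 (525 higher, 441 lower) with all arrays separate.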

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

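Of the tests in this part, those of a lower amount of mouse RNA and of a mixed-up sample or another cell line were chosen only after the result was seen, and so were the fit with skin and muscle covariates, the median of the NRF2 targets in cediranib resistant 1 and the check of how far the shift of all genes alone turns directions under median scaling.

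The response of the stroma to the 2 drugs was singled out because the difference between them was tested directly. limma called 0 mouse genes whose resistant against sensitive change differed between vandetanib and cediranib, with 1411 at an unadjusted p under 0.05. By camera with the preset correlation, the median change of cell cycle genes was 0.63 log2 units higher under vandetanib, that of macrophage and monocyte markers was 0.94 higher, and that of endothelial markers was lower by a difference of −0.73. With an estimated correlation the adjusted p of these lists was 0.779, 0.977 and 0.977. Macrophage markers were not called without cediranib sensitive 3 (0.32), and endothelial markers not without cediranib sensitive 1-2 (−0.52), cediranib resistant 2 (−0.48) or 3 (−0.39) or vandetanib sensitive 3 (−0.85).

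The 199 mouse genes called higher in cediranib resistant tumours come from arrays with 7.27-fold less mouse signal than the sensitive ones. Human RNA binding conserved mouse probes is argued against for the 151 of them with an ortholog, as a set. The odds that such a gene has a bright human ortholog were 0.544 times those of other tested genes of like level (95% interval 0.374 to 0.792). This explanation needs odds above those of other genes. The likeness of probe sequences was not used, so single genes are not covered. For 494 genes called lower the ratio was 1.14 (95% interval 0.94 to 1.39), which does not decide for them. Quantile normalization, which raises dim arrays to a shared distribution, stays open. Of the 199 genes called higher 65.8% were lower under median scaling. That setting moves the median of all genes by −1.16, and this shift alone would turn 51.3% of the 199, so the share does not decide. There 20.1% of them lay below the median of all genes. A change in stroma that leaves less mouse RNA while some genes hold their share stays open and was not tested. The groups also differ in treatment time and tumour volume. Low signal was not confined to the mouse arrays. On the human arrays the mean intensity above background per probe was 10.6, 157 and 2.64 in cediranib resistant 1 to 3. In cediranib sensitive 1 to 3 it was 61.3, 66.4 and 195. Whether the lower mouse signal stems from less mouse RNA in the tumours was thus not settled.

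Skin and hair genes were lower in resistant tumours under both drugs, with medians of −2.31 and −1.72 (adjusted p = 0.639 and 0.588 with an estimated correlation; −0.79 under vandetanib without vandetanib resistant 1 and −2.62 without vandetanib resistant 2). The list lay −2.17 log2 units from the median of the other mouse lists. A general loss of mouse RNA would allow 0.5, and the list went beyond that by more than the spread of its members (median absolute deviation, scaled to an SD, of 1.04). That use of the spread was settled after the result was seen. The list had been singled out for its fall, and quantile normalization takes out a general loss. The list thus fell further than the others, but the test does not decide on a general loss. A varying share of skin in the sampled tissue is a candidate explanation: within groups the members varied together with a mean residual correlation of 0.413, above 100% of 2000 random lists. Skeletal muscle (0.918) and endothelial genes (0.729) also varied together, so the test is not specific to skin. Whether the share of skin followed sampling or tumour size, or the skin itself responded to longer treatment, stays open.

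On the human arrays, cediranib resistant 2 had 91 genes over 3 log2 units from the sensitive mean, against 29 in cediranib resistant 1, 9 for cediranib sensitive 3 against 1 and 2, and 0 between sensitive 1 and 2. The genes switched on included AKR1B10 (intensity 7342 against 118 to 318) and AKR1C2, both known targets of the transcription factor NRF2, which led to the hypothesis of a tumour cell population with high NRF2 output. Among 22 further targets whose values had not been looked at, 15 were measured, their median difference was 1.37, above 100% of 10000 random lists, and 9 exceeded 1, with TXNRD1 at 3.35, PGD at 2.90 and NQO1 at 2.54 but GCLM at 0.01 and EPHX1 at −0.35. This is 1 array, and cediranib resistant 1 did not share it: the median of the 15 targets there was −0.06 and 0 exceeded 1, on a dim array with AKR1B10 at an intensity of 40.3. A mixed-up sample or another cell line was not excluded by any value and cannot be told apart from it, because the 91 genes rest on that single array.

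Splits of the mouse samples that keep the drugs gave as many called genes for the mean over both drugs in 2 of 60 cases, the real one with 575 included, and the highest other split gave 710. This share lies under the 5% set beforehand, but a split with more genes than the real one points to structure among the samples. The averaged pairs in these splits were also chosen after counts had been seen, so the splits do not exclude chance. On the human arrays the real split gave 0 genes, the highest of the others gave 10, and all 100 of 100 splits reached the real count, as any split reaches a count of 0, so this says nothing about chance.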

How the results depend on the processing

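The fits with all arrays separate, with vandetanib sensitive 1 to 3 averaged, with the human arrays that carried signal, and with skin and muscle covariates were chosen only after the data were seen. Signal over background limits the human arrays, since 6 of 11 carried none. On the mouse arrays median scaling moved the median of all genes under cediranib from −0.06 to −1.22, so signs there include that shift. Of single named genes under the alternatives, 823 values kept direction and side of the threshold, 692 kept direction but lost the call, and 9 reversed. These numbers leave out the changes of HGF and MET under each drug, which are given below and in which signs turned as well. The slide could not be used as a block, because the array names give none. Replicate numbers showed no pairing: deviations of resistant and sensitive mouse arrays of the same number correlated by −0.143 to 0.257 across genes.

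Leaving out each sample in turn, with a lone sample assumed to vary like the other groups, gave ranges from lowest to highest. Human gene counts were 0 to 10 for cediranib (6 with every sample), 0 to 651 for vandetanib (19), 0 to 378 for the mean (0), 0 to 458 for the difference (0) and 0 to 2524 between sensitive groups (69). Mouse gene counts were 14 to 2246 for cediranib (777), 0 to 1 for vandetanib (1), 3 to 2256 for the mean (575), 0 to 1 for the difference (0) and 0 to 86 between sensitive groups (6). List counts were 3 to 6 for human cediranib (6; 3 without cediranib sensitive 3), 6 to 11 for mouse cediranib (6; 11 without cediranib resistant 1, 10 without cediranib sensitive 3) and 5 to 8 for mouse vandetanib (5; 8 without cediranib resistant 2 or vandetanib resistant 2). Human MET under vandetanib went from −0.0618 to 0.0625.

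Median scaling gave human counts of 137 (cediranib), 0 (vandetanib), 4 (mean), 5 (difference) and 662 (sensitive groups), with shifts of all genes of −0.40, 0.00, −0.20, 0.40 and −0.78. Mouse counts were 8701, 4728, 9052, 789 and 509. It called 1 human list for vandetanib and 3 mouse lists for cediranib, and gave human HGF −0.0082 and 0.0834, human MET −0.00292 under vandetanib, and mouse Hgf −0.51 under cediranib. On the mouse arrays the sign turned for Hgf in the mean (−0.0796) and under cediranib (−0.51). Under cediranib it also turned for Elf3 (−0.19), Flt1 (−0.60), Kcnc4 (−0.16), Lep (−0.41), Plin4 (−1.50), Timp1 (−1.42), Tnfaip2 (−0.84) and Zbp1 (−0.19). The construction of this setting shows the cause: it leaves the lower mouse signal of resistant arrays in the values, with medians of all genes of −0.95 in the mean and −1.22 under cediranib. Of these genes Plin4 and Timp1 lay below that median and the others above it.

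With the log2 values the authors gave, the human counts were 0 (cediranib), 0 (vandetanib) and 32 (sensitive groups), the mouse counts 0 (vandetanib) and 0 (sensitive groups), and human MET under vandetanib −0.000262. Without background correction they were 2, 3 and 20, and 0 and 0. Without the filter on dim probes, human vandetanib gave 41 and the sensitive groups 140, and the mouse counts were 0 (vandetanib) and 15 (sensitive groups). The strict filter gave 171 human and 0 mouse genes between sensitive groups and 1 human list for cediranib. With only the compared groups in the fit the human counts were 0, 0 and 3663 and the mouse counts 0, 46 and 310 (cediranib, vandetanib, sensitive groups), with 3 human lists for cediranib and 9 mouse lists for vandetanib. Trended robust variances gave 0 human genes in these comparisons and 0 mouse genes between sensitive groups. Array weights gave 11, 0 and 3223 human genes, and 713 (vandetanib), 2091 (mean) and 368 (sensitive groups) mouse genes, with Hgf called under vandetanib at 1.16. An estimated correlation left 0 human lists for cediranib and 0 mouse lists for either drug. fry left 1 human list for cediranib, 1 for vandetanib, and 1 and 0 mouse lists. For these the cause was not tested.

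All arrays separate gave 13, 66, 21, 21 and 2106 human genes and 3094, 206, 3204, 169 and 966 mouse genes (cediranib, vandetanib, mean, difference, sensitive groups), with Hgf called at 0.70 and 1.05. More samples with near-identical pairs among them lower the estimated spread by construction. With the replicate number as a block on separate arrays, human vandetanib gave 0 genes, the human sensitive groups 1577 and human MET under vandetanib −0.13. The mouse counts with this block were 2970, 416, 3403, 47 and 822, with Hgf called at 0.70 and 0.98. Vandetanib sensitive 1 to 3 averaged gave 14, 0, 4 and 0 mouse genes (cediranib, vandetanib, mean, sensitive groups), and the skin and muscle covariates gave 0 in each, with fewer residual degrees of freedom in both. The 5 human arrays with signal gave 0 genes, 3 lists and HGF −0.00583 for cediranib, and the 4 without the weak cediranib resistant 1 gave 370 genes and MET 0.22. The last count compares 3 sensitive arrays, of which 2 are averaged, with the single array cediranib resistant 2.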

Other observations

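The tests in this part were planned, and the values per array were looked at after the data were seen.

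Skeletal muscle genes differed more among the 3 cediranib resistant tumours than between groups. On the mouse arrays the mean of the list, relative to each gene's mean over arrays, was −4.92 log2 units in cediranib resistant 2, 1.54 in cediranib resistant 1 and 0.47 in cediranib resistant 3, and lay between −1.06 and −0.64 in cediranib sensitive and between 1.27 and 1.38 in vandetanib sensitive tumours. The human array showed MYL1, a light chain of skeletal muscle myosin, at intensities of 1009, 1117 and 2548 in cediranib sensitive 1 to 3. It was at 1233 in cediranib resistant 1 and 46.0 in cediranib resistant 2. Whether this was mouse RNA on a human probe was not tested.

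Besides the NRF2 targets, cediranib resistant 2 had LCN2, an iron-binding secreted protein, at 3651 (57.5 to 67.5 in the sensitive arrays), TESC at 3453 (44.1 to 45.7), CEACAM6, an adhesion protein of epithelia, at 6986 (36.0 to 411) and CPS1, the first enzyme of the urea cycle, at 3692 (80.0 to 112). S100A8 was at 42.01 (2285 to 13725) and the imprinted RNA H19 at 45.5 (279 to 3803). Cediranib resistant 1 had S100A8 at 55.4 and did not share the higher ones, with LCN2 at 37.9 and CPS1 at 47.5, on an array whose brightest probe was 4055. These genes were chosen after their values were seen.

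Under vandetanib, mast cell genes gave a median of −0.81 (adjusted p = 0.198), with Cpa3 at −1.99 (SE 0.96), and under cediranib −0.65 (adjusted p = 0.644), with Cpa3 at −2.01 (SE 0.87) and Hdc at 2.46 (SE 0.62). Fibroblast and matrix genes gave 0.33 (adjusted p = 0.0514) and 0.18 (adjusted p = 0.375), and NK, B and T cell markers −0.05 (adjusted p = 0.749) and −0.08 (adjusted p = 0.610). None of these lists was called by camera for either drug.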
